A study of Homo sapiens with 3 samples.

How the data were processed

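RNA of HT-29 cells, a human colon adenocarcinoma line, was measured on 3 two-colour microarrays. Per the labels' protocols, cells were left to attach for 24 h, then kept for 48 h either with a PLE-extract of goldenberry (Physalis peruviana) calyx at its IC50 or with the vehicle, DMSO at 0.1% in culture medium. Total RNA was extracted with Trizol and 600 ng of labelled material per dye was hybridised, per the labels. On each of the 3 arrays the extract-treated culture carried Cy3 and the vehicle culture Cy5, per the labels, and the labels call the 3 arrays biological replicates. No array had the dyes swapped, so a gene-specific dye effect and the effect of the extract have the same sign on all 3 arrays.

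The deposited scanner files hold intensity values: the mean brightness of each spot and the median brightness of its local background in each dye, with flags for spots well above background, saturated or outlying. Per the file headers they were written by Feature Extraction 10.7.3.1 for array design 028004, with 62976 spots, of which 4259 were controls and 58717 carried 42405 different probes of 60 bases. All 3 arrays lay on 1 slide and were scanned in 1 pass. Feature Extraction's processed intensities, background-subtracted and dye-normalized with linear and lowess steps per the file headers, were used as an alternative, and its log10 ratio of Cy5 over Cy3, per the file headers, was used to find the direction of the deposited series table. That table holds log2 values by the authors; set against the scanner log10 ratios its columns had slopes of -2.32, -2.49 and -2.18 and correlations of -0.956, -0.961 and -0.942, so its sign is Cy3 over Cy5. Its columns had medians of 0.0047, 0.0021 and 0.0051 and means of 0, which shows centring on the mean; the background correction and normalization behind it are not given in the sources used here beyond the name limma in the submitters' processing notes.

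The analysis started from the spot means and local background medians. With limma 3.58.1 in R 4.3.3, background was corrected by normexp with an offset of 50 and each array was normalized by loess, with control spots and outlier-flagged spots at weight 0. Log2 ratios were turned to extract over vehicle (Cy3 over Cy5), outlier-flagged spots were left out (1.38%, 1.07% and 1.69% of spots on arrays 1, 2 and 3), and spots of the same probe were averaged. A probe was kept if it was well above background on all 3 arrays in at least 1 dye, which left 14395 probes. Each gene was represented by its brightest unsaturated probe; no spot was saturated. This gave 11994 genes, of which 1893 had more than 1 probe; of the changed genes, 1039 had more than 1 probe and 157 had probes of different sign. Through their RefSeq accessions 28588 probes received the current symbol of the GRCh38.p14 gene table, 238 old names were replaced by the gene they are a synonym of, 2812 names already were current symbols, 4768 probes kept another name of the file, and 5999 had no gene name. Probe coordinates are those of the files, on hg19 (GRCh37).

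A log2 ratio against 0 was tested for each gene with limma's lmFit and eBayes (two-sided, prior degrees of freedom 6.12) and p-values were adjusted by Benjamini-Hochberg over the 11994 genes, with a threshold of 0.05. Errors given are the SD between the 3 arrays. A named probe that was not well above background in 1 dye on all 3 arrays has no firm level there, so its log2 ratio is given with its range over alternatives. Such a ratio is open to dye bias. Gene lists (34, fixed before the data were examined, 31 of them with at least 5 measured members) were tested with camera at a preset inter-gene correlation of 0.01, and also with an estimated correlation and with fry, and adjusted over the 31 lists. At the preset correlation camera's p-values rest on the spread over genes and do not measure agreement between arrays. With an estimated correlation they rest on the few residual degrees of freedom of 3 arrays, so a list that fails there is not shown to be unshifted. Of the 34 lists, 3 held markers of other cell types. Agreement between arrays was described by correlations across genes, which are not independent replicates. With 3 arrays there are 4 sign patterns, so no permutation of signs can give a share under 0.25.

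The genes named were chosen by a rule fixed before the data were examined: the 12 largest rises and the 12 largest falls past the threshold that moved the same way on all 3 arrays and were well above background in both dyes; up to 4 members past the threshold of each list that passed its test and up to 2 of each list that did not; and 15 genes reported in any case. Clone, LOC and open-reading-frame names were left out of the first part, and 1 gene that the rule names is not reported here. Of those 15, CDKN1A and CYP1A1 (well above background in the extract channel on 2 arrays and in the vehicle channel on none) and CXCL8 (on none in either) did not pass the filter and were not tested. Members that went against their list and gene families outside the lists were chosen after their values were seen.

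Alternatives tried were other background corrections, Feature Extraction's processed signals, the authors' series table, median centring, scaling between arrays, other probe filters and summaries, other variance models, stricter thresholds and leaving out each array. The fit was tested on simulated log2 ratios of 11994 genes with 200 changed ones, for extract against vehicle. It recovered 16.4% of changes of 0.5, 92.5% of changes of 1 and 100% of changes of 2 on the log2 scale, with 3.47% false calls. A list shifted by 1 was called and no unshifted list was. In the data 5654 genes were called, so the adjusted threshold was stricter in the simulation and its recovery shares do not carry over. Simulated genes were independent and had no dye effect, so the simulation cannot show how lists of correlated genes behave. Precision is limited by the number of arrays and by signal over background: 35.7%, 28.6% and 40.5% of probes were well above background in the extract channel on arrays 1, 2 and 3, and 36.4%, 38.3% and 41.8% in the vehicle channel. Of 137 control probes tested, spike-in sequences included, none had over 50% of its spots above background in either dye on all 3 arrays (the share reached on all 3 was at most 8.57%), so no spike-in was used.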

Results

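Transcripts of HT-29 colon cancer cells treated for 48 h with a goldenberry calyx extract at its IC50 were set against those of vehicle-treated cells on 3 two-colour arrays, each hybridised with 1 extract-treated culture (Cy3) and 1 vehicle culture (Cy5). The comparison asks which transcripts differ in cells whose growth the extract inhibits. Median spot intensities were 37.6, 59.1 and 62.9 in the extract channel and 71.2, 71.4 and 90.1 in the vehicle channel on arrays 1, 2 and 3. Across the 11994 genes tested, the log2 ratios of arrays 1 and 2 correlated at r = 0.942, and those of array 3 at r = 0.812 with array 1 and r = 0.815 with array 2; genes are not independent replicates. The arrays were counted as 3 samples, as the labels call them biological replicates.

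The largest rises in extract-treated cells were those of 4 histone genes, 3 of them for H2A. H2AC19 (probe at hg19 chromosome 1, 149823132 to 149823191) rose by 3.47 ± 0.52 on the log2 scale (SD, n = 3), an 11.04-fold rise. H2AC6, H2AC7 and the linker histone gene H1-2 rose 9.25-fold, 9.04-fold and 8.89-fold. Histone genes have near-identical copies whose transcripts a probe can share, and another probe of H2AC6 gave a log2 ratio of -0.144. Other rises were those of the long noncoding RNA UCA1 (6.91-fold), the lysosomal sialidase NEU1 (6.47-fold), sulfiredoxin SRXN1 (6.46-fold), epoxide hydrolase EPHX1 (6.12-fold), ferritin light chain FTL (5.15-fold), the glutathione peroxidase GPX3 (4.97-fold; another probe gave a log2 ratio of 1.331) and IQCN (7.31-fold).

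The steepest fall was that of ANXA13, an annexin of the intestinal epithelium (hg19 chromosome 8, 124693388 to 124693447), at -4.63 ± 0.79 on the log2 scale (SD, n = 3), or 24.8-fold lower. TM4SF4 was 11.2-fold lower, the transcription factor subunit GTF3C6 10.9-fold, the matrix metalloproteinase MMP7 (hg19 chromosome 11, 102394029 to 102394088) 10.65-fold and FAM3D 10.4-fold. The histone gene H3C15 was 9.42-fold lower, the stress pseudokinase TRIB3 9.20-fold, NUPR1 8.21-fold, PHGR1 8.003-fold, BAIAP2L2 7.37-fold and the NADPH oxidase NOX1 7.15-fold. HNRNPA1, an RNA-binding protein gene, was 8.36-fold lower at its brightest probe, while its other probe gave a log2 ratio of -0.519. These rising and falling genes moved the same way on 3 of 3 arrays, as the rule for naming them required. Their limma adjusted p-values ran from 5.02e-06 to 2.90e-05.

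**Figure D1:**
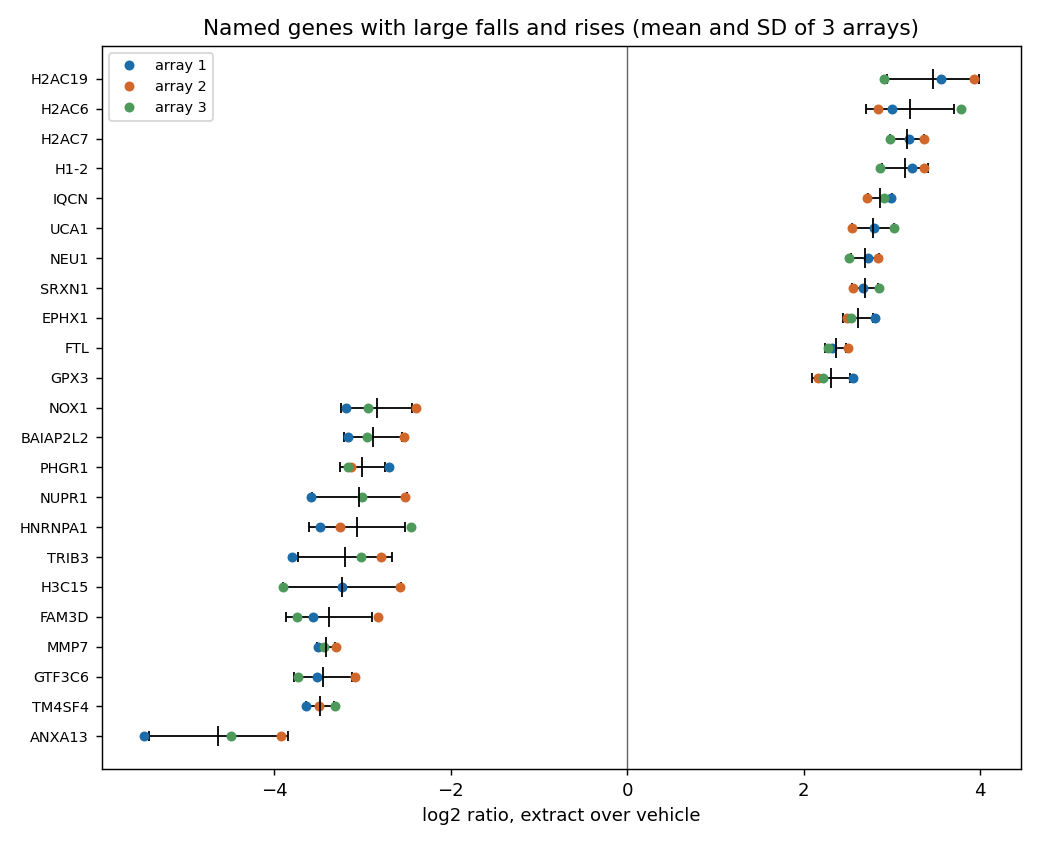
The log2 ratio of extract over vehicle is on the horizontal axis for the largest falls and rises named in the text; coloured points are the 3 arrays, and the black tick and bar are their mean and SD. ANXA13 has the largest fall (-4.63) and H2AC19 the largest rise (3.47). The arrays of each gene lie on the same side of 0, as the rule for choosing these genes required.

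In all, 5654 of the 11994 genes (47.1%) differed at adjusted p under 0.05 by limma, 2555 higher and 3099 lower in extract-treated cells; 952 of them differed by at least 1 on the log2 scale, 380 higher and 572 lower. Of the 5654, 5642 moved the same way on all 3 arrays, which calling them on these same ratios largely ensures. Among all 11994 genes tested, 8137 moved the same way on all 3. Under median centring of each array in place of loess, the median of all genes tested lay at -0.37 rather than -0.026 on the log2 scale, and 543 genes were called higher (9.78%) against 5008 lower, beside 45.2% higher under loess. With Feature Extraction's signals 2897 were higher and 2645 lower. With the authors' deposited log2 values 3164 were higher and 2845 lower, and among genes above background in both channels 2428 and 2278. Which direction had more calls thus depended on the processing. With the dyes in the same orientation on all 3 arrays, the direction of any gene includes its dye effect.

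The ATF4 and integrated stress response list, genes induced by amino acid shortage and other stresses, fell more than any other list. Of 22 measured members 20 fell, none rose and 2 did not pass, with a median log2 ratio of -1.86 (camera adjusted p = 1.69e-10; adjusted p = 0.606 with an estimated correlation). Adjusted over the list alone, 20 were lower and 1 was higher. Serine synthesis gene PSAT1 fell to a log2 ratio of -2.63 ± 0.30 (SD, n = 3), the glutathione-degrading enzyme gene CHAC1 to -2.60 ± 0.10, DDIT3 to -1.08 ± 0.47 and ATF3 to -0.73 ± 0.29. Other probes of CHAC1 and ATF3 gave -0.801 and -0.064.

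Genes of the NRF2 antioxidant programme rose. Of 26 measured members 19 rose, 2 fell and 5 did not pass, with a median of 0.86 (camera adjusted p = 1.61e-08; adjusted p = 0.570 with an estimated correlation); adjusted over the list alone, 22 were higher and 2 lower. The quinone reductase NQO1 rose by 1.25 ± 0.48 (SD, n = 3) and heme oxygenase HMOX1 by 0.72 ± 0.32; the call of HMOX1 was lost under median centring (adjusted p = 0.130, range over alternatives 9.49e-10 to 0.130). Named after their values were seen, the falling members were SLC7A11, the cystine transporter that is also in the ATF4 list (-2.18), and UGDH (-0.56). The glutathione metabolism list had 13 members higher, 6 lower and 5 not past the threshold of 24, with a median of 0.40 (camera adjusted p = 0.0224; adjusted p = 0.570 with an estimated correlation), but under median centring 5 were higher and 8 lower (median -0.086), with no filter on dim probes the median was 0.138, and its test did not pass with Feature Extraction's processed signals (adjusted p = 0.0679, range over alternatives 0.00926 to 0.0679). Adjusted over the list alone, 14 were higher and 6 lower, among them the peroxidase GPX2 (3.19-fold higher) beside GPX3.

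Mitotic genes fell throughout: all 29 measured members of the mitosis and G2/M list were lower, also when adjusted over the list alone, with a median of -1.11 (camera adjusted p = 4.52e-13; adjusted p = 0.570 with an estimated correlation). Cyclin CCNB2 fell to a log2 ratio of -2.08 ± 0.04 (SD, n = 3), the spindle midzone protein gene PRC1 to -2.04 ± 0.40, CENPF of the kinetochore to -2.03 ± 0.28, UBE2C to -1.79 ± 0.21, CCNB1 to -1.62 ± 0.27 and the proliferation marker MKI67 to -0.88 ± 0.38. In the DNA replication and G1/S list 24 of 31 members fell, 1 rose and 6 did not pass (median -0.60, camera adjusted p = 2.08e-07; adjusted p = 0.570 with an estimated correlation), with the same counts adjusted over the list alone. The thymidylate synthase gene TYMS fell 4.61-fold, RRM1 of ribonucleotide reductase 3.30-fold, CDC45 2.90-fold and GINS1 2.31-fold. MYC was 3.01-fold lower, whereas cyclin D gene CCND1 had a log2 ratio of 0.30 ± 0.13 (adjusted p = 0.0453) that became -0.058 under median centring. The call of CCND1 was also lost with scaling between arrays and without replicate 1 or 2 (range over alternatives 0.00155 to 0.824).

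Ribosomal protein, aminoacyl-tRNA synthetase and purine synthesis genes fell, with list medians further below 0 on array 1 than on array 3. None of these lists passed fry's directional test (fry adjusted p = 0.0849, 0.123 and 0.0849). Of 32 cytosolic ribosomal protein genes 23 fell, none rose and 9 did not pass, the same adjusted over the list alone, with a median of -0.66 (camera adjusted p = 3.80e-06; adjusted p = 0.713 with an estimated correlation). With Feature Extraction's processed signals 13 were lower and 2 higher (median -0.349), and under median centring 32 were lower (median -1.32). The list's median was -0.87, -0.56 and -0.48 on arrays 1, 2 and 3. RPL3 fell 3.23-fold, RPL6 2.69-fold, RPL5 2.48-fold and RPS6 2.28-fold. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, fell for 12 of 20 members and none rose, the same adjusted over the list alone (median -0.59; array medians -0.78, -0.64 and -0.34; camera adjusted p = 0.000478; adjusted p = 0.777 with an estimated correlation). IARS1 fell 3.71-fold, TARS1 3.08-fold, MARS1 2.87-fold and SARS1 2.79-fold, although other probes of IARS1, MARS1 and SARS1 gave log2 ratios of -0.835, -0.142 and -0.221. Purine synthesis genes fell for 7 of 12 members, 1 rose and 4 did not pass (median -0.40; array medians -0.62, -0.55 and -0.14; camera adjusted p = 0.0224; adjusted p = 0.606 with an estimated correlation), and without array 2 the list did not pass (adjusted p = 0.135, range over alternatives 0.000499 to 0.135). Purine genes called lower numbered 4 with Feature Extraction's signals and 11 under median centring. Adjusted over the list alone, 8 were lower and 1 higher, among them PAICS (2.33-fold lower) and GMPS (1.92-fold lower).

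Interferon-stimulated genes rose: 15 of 19 measured members were higher, none was lower and 4 did not pass, with a median of 0.63 (camera adjusted p = 3.96e-06; adjusted p = 0.570 with an estimated correlation). Adjusted over the list alone, 15 were higher and 1 lower. The ubiquitin-like modifier gene ISG15 rose by 1.87 ± 0.14 on the log2 scale (SD, n = 3), the transcription factor gene IRF7 by 1.85 ± 0.18, IFI6 by 1.75 ± 0.21 and IFIT1 by 1.62 ± 0.48. In the autophagy and lysosome list 12 of 20 members rose, 2 fell and 6 did not pass, the same adjusted over the list alone (median 0.51, camera adjusted p = 0.000125; adjusted p = 0.570 with an estimated correlation). The autophagy receptor gene SQSTM1 rose 4.06-fold, the proton pump subunit gene ATP6V0D1 3.12-fold, MAP1LC3B 2.95-fold and LAMP2 2.88-fold, although another probe of LAMP2 gave a log2 ratio of 0.159. Named after their values were seen, the falling members were TFEB (-0.46), a transcription factor of lysosomal genes, and the receptor gene NBR1 (-0.66). Under median centring 7 members of each of these lists were called higher and 1 and 3 lower, with list medians of 0.305 and 0.037.

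Differentiation genes of the intestinal epithelium fell. Of 10 measured goblet and secretory cell genes 8 fell, none rose and 2 did not pass, the same adjusted over the list alone (median -0.73, camera adjusted p = 0.000684; adjusted p = 0.606 with an estimated correlation). The trefoil factor gene TFF3 fell 5.73-fold (another probe gave a log2 ratio of -1.694), REG4 3.05-fold (another probe gave -0.557), the secretory lineage transcription factor gene SPDEF 2.82-fold and AGR2 2.25-fold; in extract-treated cells REG4 was well above background on 1 array and SPDEF on 2. Of 9 enterocyte genes 6 fell, none rose and 3 did not pass, and 7 fell when adjusted over the list alone (median -0.58, camera adjusted p = 0.0184; adjusted p = 0.606 with an estimated correlation). The fatty acid binding protein gene FABP1 fell to a log2 ratio of -1.82 ± 0.59 (SD, n = 3), with -5.041 to -1.528 over alternatives. It was not well above background in extract-treated cells on any array. CEACAM1 fell 2.67-fold (another probe gave a log2 ratio of -0.101), LGALS4 2.24-fold and VIL1 1.52-fold. With no filter on dim probes the median of the goblet list was -0.226 and that of the enterocyte list -0.024, and both lists still passed.

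**Figure D2:**
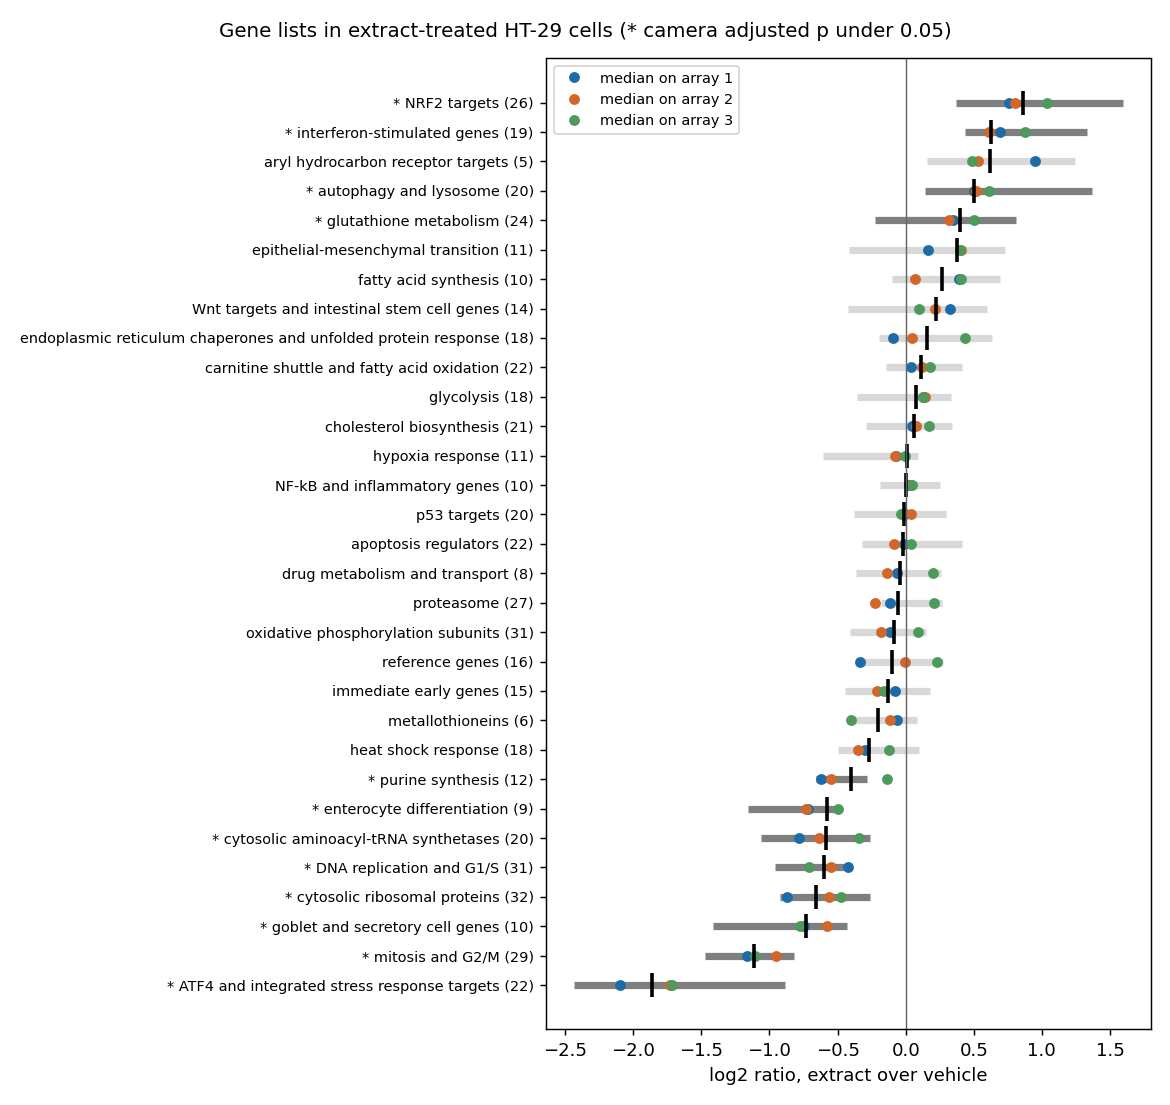
For each of the 31 gene lists tested (measured members in brackets), the black tick is the median log2 ratio of extract over vehicle, the bar spans the quartiles of the members, and coloured points are the medians on the 3 arrays; asterisks and dark bars mark the 12 lists past the threshold. Medians run from -1.86 for the ATF4 list to 0.86 for NRF2 targets, and that of glutathione metabolism (0.40) turned to -0.086 under median centring.

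The remaining 19 lists did not pass (camera adjusted p from 0.0827 to 0.929). Aryl hydrocarbon receptor targets came closest, with 3 of 5 members higher and none lower, NQO1 and the glucuronosyltransferase gene UGT1A6 (2.36-fold; another probe gave a log2 ratio of 0.69) among them. Among 20 p53 targets 6 rose and 6 fell, with PLK2 3.45-fold and the proapoptotic gene BBC3 1.98-fold lower; among 22 apoptosis regulators 6 rose and 6 fell, with CASP9 2.86-fold and BMF 2.34-fold higher. In the heat shock list 2 of 18 rose and 7 fell: HSPA1A was 2.37-fold higher, the mitochondrial chaperone gene HSPD1 3.17-fold lower and HSPA8 2.79-fold lower. Endoplasmic reticulum chaperone and unfolded protein response genes had 8 higher and 3 lower of 18, with XBP1 2.19-fold lower and SDF2L1 1.84-fold higher, and HSPA5 had a log2 ratio of 0.20 ± 0.36 (SD, n = 3) that did not pass (adjusted p = 0.293). Under median centring none of this list was higher and 7 were lower (median -0.303). The call of SDF2L1 was lost under median centring (adjusted p = 0.166, range over alternatives 2.42e-10 to 0.166).

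Of cholesterol synthesis genes 7 of 21 rose and 5 fell (LSS 2.27-fold higher, ACAT2 2.21-fold and HMGCS1 1.325-fold lower), of fatty acid synthesis genes 4 of 10 rose and 2 fell, of carnitine shuttle and fatty acid oxidation genes 5 of 22 rose and 3 fell (HADH 2.27-fold lower, ACADVL 2.25-fold higher), and CPT1A had a log2 ratio of 0.08 ± 0.19 (SD, n = 3, adjusted p = 0.632). Glycolysis genes rose for 6 of 18 members and fell for 4, with HK2 2.92-fold and LDHB 2.76-fold lower, and oxidative phosphorylation genes rose for 7 of 31 and fell for 9. Hypoxia genes rose for 2 of 11 members and fell for 3, with CA9 8.09-fold lower and ADM 2.71-fold higher. Counts were 7 rises and 4 falls of 14 for Wnt targets and stem cell genes (RNF43 2.86-fold higher), 6 and 3 of 11 for the epithelial-mesenchymal transition list (KRT8 3.26-fold higher; another probe gave a log2 ratio of 0.402), 7 and 4 of 27 for the proteasome, 1 and 3 of 6 for metallothioneins, 1 and 2 of 8 for drug metabolism, 1 and 1 of 10 for NF-kB genes, and 3 and 6 of 15 for immediate early genes. The largest change in the epithelial-mesenchymal transition list was the fall of MMP7 (10.65-fold). That list was not split into epithelial and mesenchymal markers, so its counts give no direction of a transition. Under median centring rises and falls were 2 and 9 for cholesterol synthesis, 1 and 4 for fatty acid synthesis, 4 and 6 for the carnitine list, 1 and 8 for glycolysis, and 1 and 21 for oxidative phosphorylation. They were 0 and 17 for the proteasome, 0 and 8 for p53 targets, 3 and 9 for apoptosis regulators, 2 and 4 for Wnt targets, 2 and 4 for the epithelial-mesenchymal transition list, and 2 and 1 for aryl hydrocarbon receptor targets. For heat shock they were 1 and 11, and for hypoxia 2 and 5. For metallothioneins, drug metabolism and NF-kB genes they were 0 and 4 each, and for immediate early genes 0 and 7.

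The HMGCS1 log2 ratio of -0.41 ± 0.30 (SD, n = 3, adjusted p = 0.0335) was not called with Feature Extraction's signals, with no filter on dim probes, or without replicate 1 or 2 (range over alternatives 6.58e-06 to 0.2498). In the lists above, the immediate early gene DUSP6 was 2.62-fold lower, the respiratory complex I genes NDUFS1 2.11-fold lower and NDUFA2 2.32-fold higher. ACACA of fatty acid synthesis was 1.92-fold lower, HPRT1 of purine salvage 1.88-fold lower, the metallothionein MT1E 1.59-fold lower and the transporter ABCG2 1.54-fold lower. The calls of FASN (1.90-fold higher), SOD2 (1.86-fold), ABCC3 (1.75-fold), PSMD3 (1.73-fold), PSMC2 (1.64-fold), MT2A (1.52-fold) and APRT (1.502-fold) were lost under median centring (adjusted p from 0.0587 for SOD2 to 0.989 for APRT). IER3 was 1.27-fold lower (adjusted p = 0.0216), a call lost under 5 alternatives (range over alternatives 0.000485 to 0.169). The median, mean or test differed in sign for the apoptosis, glycolysis, drug metabolism, proteasome and hypoxia lists.

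Reference genes rose for 4 of 16 members and fell for 4, with B2M 2.43-fold higher and IPO8 2.18-fold lower. Under median centring 1 was higher and 11 were lower (median -0.653). In extract-treated cells ABCG2, CA9, HK2, IPO8 and MKI67 were well above background on 2 of the 3 arrays. Of the markers of other cell types no fibroblast marker was measured, and the leukocyte markers CD14 and CD79A did not pass, with log2 ratios of -0.16 and 0.02. CD14 was called lower under 1 alternative (limma adjusted p = 0.00863). Of the hepatocyte and kidney markers, TTR fell to a log2 ratio of -2.27 ± 0.505 (SD, n = 3), with -4.761 to -1.981 over alternatives. It was not well above background in extract-treated cells on any array. SERPINA1 was 2.23-fold lower.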

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

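The regression on base composition was chosen after the data were seen. Of 113 named genes, 100 kept their side of the threshold and, where called, their direction under every alternative run for them; the exception in direction among called genes was CCND1, at -0.058 under median centring. The uncalled HSPA5, CPT1A and CD79A took either sign (-0.253 to 0.366, -0.304 to 0.266 and -0.46 to 0.148). The 12 passing lists kept their direction by camera throughout, and 10 of them also their side of the threshold; the exceptions were glutathione metabolism with Feature Extraction's signals and purine synthesis without replicate 2. The aryl hydrocarbon receptor list passed under 6 alternatives. Requiring a log2 ratio of at least 1 left 952 genes, by construction. With an estimated inter-gene correlation 0 lists passed camera (lowest adjusted p 0.570). A high correlation cannot be the whole cause. Glutathione metabolism had an estimated correlation of -0.017, under the preset 0.01, yet its unadjusted camera p went from 0.00869 to 0.101. That test also rests on the few residual degrees of freedom of 3 arrays, so failing it does not show that correlation removed a result. fry's mixed test, which asks whether members change either way, called all 31. fry's directional test called 10 lists, 9 of them among the 12. The ribosomal protein, aminoacyl-tRNA synthetase and purine synthesis lists failed it. It also called immediate early genes (fry adjusted p = 0.0247), which did not pass camera. Leaving out each array gave 3793 to 7362 genes, the highest without array 3, and 12 to 13 lists; 5596 of the 7362 were among the 5654. Median centring moved the median of all genes to -0.37; relative to that median the 12 lists kept their sign under all 6 other scalings that alter the ratios (Aquantile leaves them unchanged). With Feature Extraction's signals 2 ribosomal protein genes and 1 ATF4 list member were called higher and 1 interferon-stimulated gene lower (also under median centring), and with the authors' deposited log2 values 1 member each of the ribosomal protein, ATF4 and enterocyte lists was called higher. The mean correlation between arrays was 0.856 (0.812 to 0.855 under alternatives). The slide could not be tried as a block, since the arrays share 1 slide. No paired analysis was possible beyond the ratio within each array, because each array already pairs an extract culture with a vehicle culture. Among the 5654 changed genes, 207 that were lower were not well above background in extract-treated cells on any array, and 24 that were higher were not in vehicle cells. With no filter on dim probes 5695 of 31902 genes were called.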

Other observations

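All gene families here, and the tests on second probes, base composition of the lists, swapped dyes and sign patterns, were chosen only after results they bear on had been seen. Histone genes moved mostly in opposite directions when H2A, H2B and H1 genes were set against H3 and H4 genes, with exceptions in both groups. Of 34 measured H2A, H2B and H1 genes 24 were higher and 6 lower, with a median log2 ratio of 0.78 (camera adjusted p = 1.68e-06 over 25 families; adjusted p = 0.621 with an estimated correlation), and of 24 H3 and H4 genes 4 were higher and 14 lower, with a median of -0.86 (camera adjusted p = 0.00256; adjusted p = 0.793 with an estimated correlation). H2BC12 rose by 2.11 and H2BC5 by 1.91 on the log2 scale, whereas H4C3 and H4C13 fell, to log2 ratios of -2.68 and -2.49. The probes of H2AC19 (log2 ratio 3.47) and H3C15 (-3.24) lie next to each other on chromosome 1, from 149823132 to 149824685 on hg19. Among H2A genes H2AC20 fell by 2.06. H1 genes were mixed: H1-2 rose by 3.15 and H1-4 by 0.99, while H1-5 and H1-3 fell, to log2 ratios of -2.30 and -1.29. Of the 4 H3 and H4 genes that were higher, H4C15 rose by 0.92 and H4C6 by 0.61.

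Genes of hnRNP proteins, which bind and process nuclear RNA, fell for 15 of 20 members and none rose (median -0.80, camera adjusted p = 7.30e-05; adjusted p = 0.676 with an estimated correlation); HNRNPH1 and HNRNPA3 fell, to log2 ratios of -1.70 and -1.62. Kinesin genes fell for 14 of 21 (median -0.57, camera adjusted p = 0.000295; adjusted p = 0.676 with an estimated correlation) and nucleoporin genes for 10 of 20 (median -0.36, camera adjusted p = 0.0136; adjusted p = 0.854 with an estimated correlation), and none of either rose; with the authors' deposited log2 values 1 nucleoporin and 1 hnRNP gene were called higher, and with Feature Extraction's signals 1 nucleoporin gene. Class I HLA and antigen-processing genes were higher for 10 of 15 and lower for 2 (median 1.00, camera adjusted p = 0.00329; adjusted p = 0.676 with an estimated correlation), with HLA-B at 1.35, HLA-C at 1.23 and the peptide transporter TAP1 at 1.19 (log2); class I transcripts are near-identical to probes of their relatives. Subunits of the V-type ATPase, the lysosomal proton pump, were higher for 9 of 14 and lower for 1 (median 0.49, camera adjusted p = 0.00256; adjusted p = 0.676 with an estimated correlation), with ATP6V0A1 at 1.47. Under median centring 7 HLA genes were higher and 5 lower (median 0.42), 5 V-type ATPase genes higher and 3 lower (median 0.198), 16 H2A, H2B and H1 genes higher and 8 lower (median 0.347), and 0 H3 and H4 genes higher and 19 lower (median -1.266). Each median kept its sign under median centring, Feature Extraction's signals and the authors' series table.

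In all, 5654 genes and 12 lists differed while the dyes lay in the same orientation on all arrays. A dye effect of single probe sequences is argued against by second probes: of 996 changed genes with a second probe sharing no 20 bases with the first, it moved the same way for 86.9% (exact 95% interval 84.6% to 88.9%), where such an effect predicts under 60%; the share was 60.6% among 832 genes not past the threshold. Of the 996 second probes 562 were themselves called the same way, and for changes of at least 1 the second probe's log2 ratio was a median 0.556 of the first's. Base composition explained 6.88%, 5.76% and 0.172% of the variance of the ratios on arrays 1, 2 and 3, and 12 of the 12 lists still passed the same way after it was regressed out, so it is not the whole cause. A transcript-level dye effect cannot be told apart from the extract, since 0 arrays had swapped dyes. Of the 4 sign patterns of the 3 arrays, 1 (the real one) gave as many genes (5654, highest other 0) and 1 as many passing lists (12, highest other 11), and 4 patterns are too few for a share under 0.05. With the sign of array 1 or of array 2 reversed, 11 lists still passed although 0 genes were called. With array 3 reversed 6 passed. The camera p-values at the preset correlation thus do not measure agreement between the 3 arrays.

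The ribosomal protein list fell, and less on array 3. The list's median lay at or under the 1.11th percentile of 10000 random lists matched on bins of mean intensity on each array (the highest, 1.11, on array 3). This argues against a signal-level trend shared by all genes of those bins. The list was among the brightest (mean log2 intensity 14.97, against 8.496 for all genes). Matching within a bin was coarse there, so a trend among the brightest genes is not excluded. The median of array 1 lay -0.373 from that of array 3 after the regression on base composition (bootstrap SD over the list's genes 0.079) and -0.396 before. Resampling genes treats them as independent, although their estimated correlation was 0.514, and does not measure a spread between arrays. The regression thus hardly changed the difference. For this list, base counts entered linearly thus accounted for little of the difference between arrays 1 and 3. The difference passed the bound of 0.3 set beforehand by less than 1 SD, so by that bound the test could not tell. A part from base composition stays open. The arrays belong to the same group, so no biological explanation of their difference was tested.

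For the histone split, base composition does not account for the difference of the medians (1.64 before and 1.69 after the regression, bootstrap SD over genes 0.398). Signal level gave no such difference either, which lay at the 100th percentile of 10000 matched random lists (upper bound of their central 95% 0.354). Averaging probes that share at least 45 of 60 bases into 31 and 14 clusters left a difference of 1.92 (bootstrap SD over clusters 0.535). That argues only against near-identical probe sequences counted many times as the whole cause. Probes at different positions of near-identical copies were not merged, so repeated counting of shared transcripts stays open. A difference between both histone groups in response to the extract remains a hypothesis, and a transcript-level dye effect stays open here too.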
